A study of Rattus norvegicus with 72 samples.

How the data were processed

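Gene expression was measured in dorsal root ganglia of rats on Affymetrix rat expression arrays, per the labels, after sham surgery or after a sciatic nerve lesion labelled proximal or distal, at 8 times. RNA was extracted with a Qiagen RNeasy kit and labelled with biotin, per the labels' protocols. The deposited values are log2 intensities per probe set, made by the authors with RMA (background correction, quantile normalization and summarization over the probes of a set), per the submitters' processing notes, with a version not given in the sources used here. Whether all 72 arrays were normalized together is not given in the sources used here. Every column of values was used, and lesion, time and array letter came from the labels.

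The table held 31099 probe sets, of which 57 control probe sets were left out. The platform annotation gave 1 gene symbol to 20826 probe sets, several symbols to 436 and none to 9780, and only probe sets with 1 symbol were named. Of the named probe sets 20758 matched a RefSeq gene by Entrez identifier, and 0 symbols changed. Each of the 14217 named genes was represented by its probe set with the highest mean over all arrays, and probe sets with a mean below the 25th percentile (5.46 log2) were left out, which left 12276 genes. A gene can pass this filter and lie below its level in 1 group. Its log2 difference can then understate the change, and its fold is given as a lower bound, the mean of the brighter group over the filter level. Mapk3, named in the rule below, was not among the named probe sets.

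Tests used limma 3.58.1 in R 4.3.3, and files were read with the package data.table in version 1.17.8. A model with 1 mean for each of the 24 groups was fitted to all 72 arrays (48 residual degrees of freedom), with empirical Bayes moderation and a trend with mean expression, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. All tests were two-sided. A window comparison averaged the differences at the hours of the window with equal weight, so its log2 fold change can differ slightly from the difference of the window means printed beside it, and SE is the moderated standard error. Where a group had 1 array, its array was assumed to vary like those of the other groups. Time within sham was a moderated F test over all sham times.

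Gene lists were tested with camera, which compares the genes of a list with all other tested genes, with a preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over 28 lists and 6 comparisons. The lists were injury-induced and regeneration-associated genes, immediate-early genes, nociceptor and sensory genes, JAK-STAT signalling, chemokines and cytokines, interferon response, glucocorticoid-responsive genes, circadian clock, cholesterol biosynthesis, unfolded protein response, heat shock proteins, importins, dynein and kinesin genes, MAP kinases, tubulins and growth cone proteins, cell cycle, ribosomal proteins and oxidative phosphorylation. Marker lists covered sensory neurons, satellite glia, Schwann cells, macrophages, neutrophils, lymphocytes, erythrocytes, endothelium, fibroblasts, pericytes, adipocytes, skeletal muscle and spinal cord. Of 31 lists, 3 had fewer than 5 tested genes and were not tested as lists.

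The comparisons, the windows, the model, the filter, the lists and the rule for genes named in the text were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with one direction at every time of the window, the 4 members of each list with the smallest p, and a set of injury genes whatever their values (Atf3, Jun, Sox11, Sprr1a, Gap43, Gal, Npy, Stat3, Gadd45a, Csrp3, Fos, Egr1, Socs3, Il6, Scn10a, Trpv1, Kpnb1, Vim, Mapk3). The text gives part of the genes the rule took.

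Alternatives planned beforehand were no filter and a filter at the 50th percentile (7.01 log2), another quantile normalization, array weights, leaving out arrays whose letter is followed by o, every probe set in place of 1 per gene, the array letter as a replicate block, fitting only the arrays compared, pooling all sham arrays, other probe sets of a gene, an estimated correlation for the lists, and leaving out each array in turn. Technical sets were found by hierarchical clustering (Ward) of the arrays on the probe sets below the filter, and entered as a fixed block where lesion and set could be separated and as a random block (duplicateCorrelation) elsewhere. The labels do not say what a letter marks. The pairing of arrays by letter was checked by the correlation of their deviations from the group means, with a limit of 0.1 for every pair. It held for proximal and sham arrays at 1 h (0.696, 0.509 and 0.478), all in 1 technical set, and at 18 h (0.618, 0.714 and 0.799), where c lay in another set than a and b, and at no other hour with 3 pairs. At 18 h both groups were split over the sets in the same way, so pairing there cannot be told from technical set. The letter was entered as a block within these hours for proximal against sham. These blocks, the fits without the arrays labelled sham 12 h b and sham 16 h a, the late window without 18 h and a comparison of late with early distal arrays, also with the difference between 3' and 5' probe sets of gapdh or actin as a covariate for RNA quality, were chosen after the data were seen.

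The steps were tested on simulated data for the late proximal comparison with 12276 genes. Of 50 genes shifted by each size, 82% were called at a log2 change of 0.5, 98% at 1, 100% at 1.5 and 100% at 2, and 10 of 12057 unchanged genes were called. The noise was drawn independently for each gene and array, without technical sets or pairs of arrays, so the real arrays can give more false calls. With shifts between technical sets alone, 5944 genes were called between distal and sham arrays at 8 h without a block and 0 with technical set as a block. The highest correlation between arrays was 0.998 and at most 0.106% of values were identical between arrays, so none was counted as deposited more than once.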

Results

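Dorsal root ganglia hold the cell bodies of the sensory neurons whose axons run in the sciatic nerve, so a crush of the nerve injures these neurons at a distance. RNA from the lumbar ganglia L4 and L5 of Wistar rats aged 8 to 12 weeks was measured on 72 Affymetrix arrays. Of these 21 were labelled sham, 22 proximal and 29 distal, the last 2 kinds after a crush at different sites on the nerve. Arrays came from 8 times between 1 and 28 h, which made 24 groups of lesion and time. The early window held 1, 3 and 8 h (9 sham, 9 proximal and 12 distal arrays), the middle window 12 and 16 h (3, 4 and 5 arrays) and the late window 18, 24 and 28 h (9, 9 and 12 arrays). Sham groups had 3 arrays except 2 at 12 h and 1 at 16 h, proximal groups 3 except 2 at 12 and 16 h, and distal groups between 2 and 6. Values were log2 intensities from 3.27 to 14.64 with array medians from 6.88 to 7.08. The labels do not say that arrays are separate animals, so p-values measure the spread between arrays, and the number of arrays limits the precision. The series title concerns signals that travel from an injured axon back to the nucleus, so the comparisons ask which genes of the ganglion differ after a lesion at each site, at which hour, and between the sites.

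Probe sets too dim to be tested separated the arrays into 4 technical sets, called A to D here and found after the data were seen. Set A held 27 of the 29 distal arrays and no other array. Set B held 4 sham, 4 proximal and 1 distal array, set C 8 sham, 9 proximal and 1 distal array, and set D 9 sham and 9 proximal arrays. The interquartile range of all log2 values ran from 3.51 to 3.73 in set A, from 3.60 to 3.78 in set B, from 2.73 to 3.14 in set C and from 3.13 to 3.39 in set D. The first principal component of the tested genes held 38.5% of their variance, and technical set accounted for a share of 0.955 of that component against 0.558 for lesion. Proximal and sham arrays of an hour fell into the same sets at all hours but 16 h, where sham had 1 array. Distal and sham arrays shared sets only through 2 distal arrays, 1 at 1 h in set B and 1 at 18 h in set C.

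**Figure D1:**
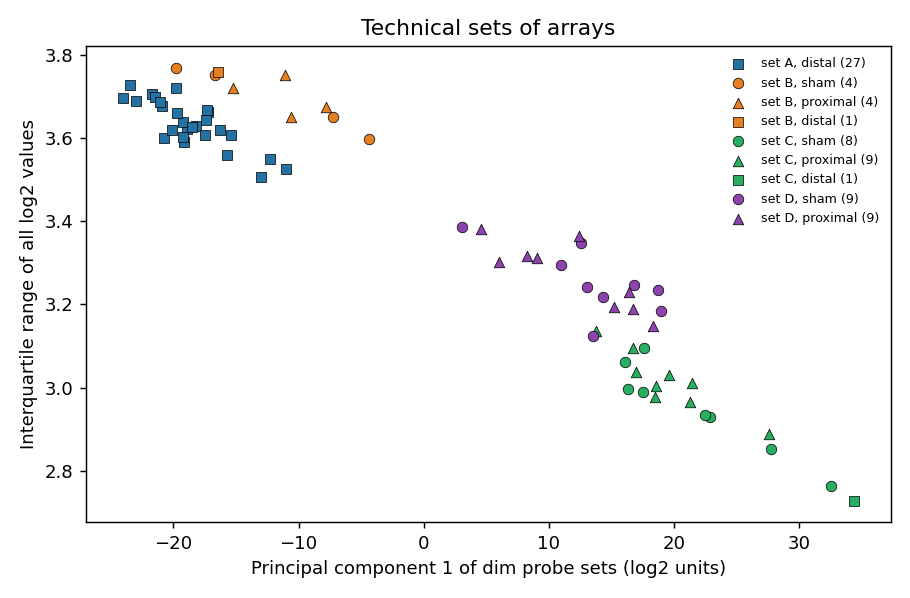
Each point is 1 of the 72 arrays, placed by the first principal component of the dim probe sets (log2 units, horizontal) and by the interquartile range of all its log2 values (vertical), with colour for technical set and shape for lesion. Set C lies lowest, between 2.73 and 3.14, and 27 of the 29 distal arrays form set A on their own.

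Neuronal injury genes rose in the ganglion 18 to 28 h after the proximal lesion. Atf3, a stress-induced transcription factor that marks axotomised neurons, had a mean log2 intensity of 12.41 ± 0.28 (SD, n = 9) after the proximal lesion and 8.79 ± 0.99 (SD, n = 9) after sham. That was a 12.3-fold rise (log2 fold change 3.62, SE 0.30, adjusted p = 1.69e-14). Il6, a cytokine that signals through gp130, rose at least 5.35-fold (log2 3.46, SE 0.23, adjusted p = 5.63e-18), a lower bound because its sham mean of 4.43 lay below the filter level of 5.46. Reg3b, a secreted lectin of regenerating tissues, rose 9.11-fold (log2 3.19, SE 0.21, adjusted p = 2.87e-18). The neuropeptide gene Vip rose at least 5.88-fold (log2 2.63, SE 0.12, sham mean 5.39), the cell stress gene Gadd45a 5.11-fold (log2 2.35, SE 0.19), and Sox11, a transcription factor of developing and regenerating neurons, by the same 5.11-fold (log2 2.35, SE 0.19). For each of these 6 genes all 9 proximal arrays lay above all 9 sham arrays. Others of the 10 largest rises were Tnfaip6, a hyaluronan-binding protein of inflamed tissue (log2 3.11), the epithelial cytokine gene Tslp (2.85), Flrt3, a membrane protein of neurite growth (2.70), and Reg3a (2.59).

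The largest falls were smaller. Racgap1, a gene of cell division, fell by 1.32 on the log2 scale (SE 0.11, adjusted p = 1.69e-14), and the receptor genes Adra2c, for an adrenergic receptor, and Htr1d, for a serotonin receptor, fell by 1.01 (SE 0.11) and 0.95 (SE 0.10). In all 9 proximal arrays these 3 genes lay below every sham array. Of the 10 largest falls, 4 more were those of the activin subunit gene Inhbb (log2 -0.94), the homeodomain factor gene Isl2 (-0.84), the cadherin gene Cdh10 (-0.84) and the signal transducer gene Smad9 (-0.84). The others were the potassium channel gene Kcna4 (-0.82), LRRTM1 (-0.80), which encodes a synaptic membrane protein, and Nog, a secreted antagonist of bone morphogenetic proteins (-0.80). The Nog call was lost when only the arrays compared were fitted and when all sham arrays were pooled. Over all 12276 genes tested, limma called 1192 (657 higher and 535 lower). Of these, 83 differed by at least 2-fold, 81 of them higher and 2 lower. With technical set as a block 2336 genes were called (1176 higher and 1160 lower), and after another round of quantile normalization 1803 (837 higher and 966 lower).

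**Figure D2:**
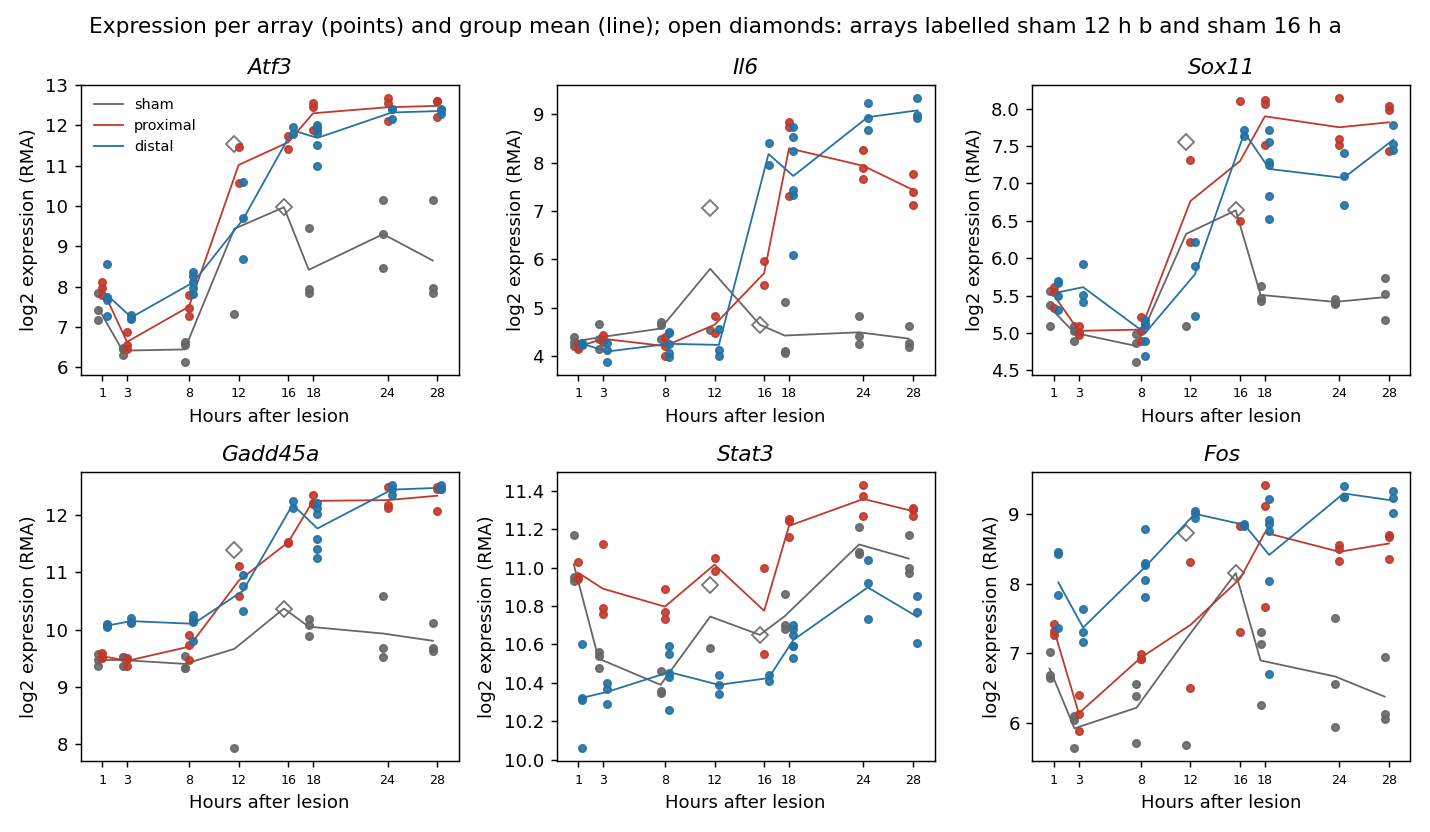
Log2 expression (vertical) of 6 genes by hours after the lesion (horizontal), with 1 point per array, a line through the group means and open diamonds for the arrays labelled sham 12 h b and sham 16 h a. Atf3 stood at a mean of 7.50 in proximal arrays at 8 h (n = 3) and 12.30 at 18 h (n = 3), against 6.44 and 8.42 in sham arrays.

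Among the gene lists fixed beforehand, 4 shifted upwards in the late proximal comparison under the preset correlation and also under an estimated one. The injury-induced and regeneration-associated list had 37 of 48 genes higher, 0 lower and 11 not called, and 39 higher when adjusted over the list alone. Its median was 0.80 (camera adjusted p = 2.96e-68, and adjusted p = 1.27e-07 with an estimated correlation). Members included Adcyap1, a neuropeptide gene (3.44-fold, log2 1.78, SE 0.10), Gal for the neuropeptide galanin (2.21-fold, log2 1.14, SE 0.09), Jun for an AP-1 transcription factor (2.08-fold, log2 1.05, SE 0.14) and Csrp3 for a muscle LIM protein (log2 1.83, SE 0.21). Smaller rises were those of Npy for neuropeptide Y (log2 0.77), Sprr1a (0.65) and the growth cone gene Gap43 (0.21, SE 0.05). The immediate-early list had 14 of 31 genes higher, 1 lower and 16 not called, the same as when adjusted over the list alone (adjusted p = 3.3e-10, and adjusted p = 0.0329 with an estimated correlation). Fos rose 3.85-fold (log2 1.95, SE 0.28), the stress gene Gadd45g 3.47-fold (log2 1.80), the cysteine-serine-rich nuclear protein gene Csrnp1 2.39-fold (log2 1.26), Myc 2.20-fold (log2 1.14) and Egr1 1.65-fold (log2 0.73). A dimmer probe set of Fos did not follow (log2 -0.024), and without the 18 h arrays Egr1 was no longer called.

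The list of JAK-STAT and gp130 cytokine signalling had 9 of 19 genes higher, 0 lower and 10 not called, and 11 higher when adjusted over the list alone (adjusted p = 1.34e-10, and adjusted p = 0.00607 with an estimated correlation). Its feedback inhibitor genes rose: Socs3 2.14-fold (log2 1.09, SE 0.11) and Cish 1.65-fold (log2 0.72, SE 0.11). Ptpn2, for a phosphatase of the pathway, rose 1.97-fold and Stat3, for the transcription factor itself, 1.25-fold (log2 0.32, SE 0.06). The list of chemokines, cytokines and NF-kappaB targets had 9 of 22 genes higher, 0 lower and 13 not called, and 10 higher when adjusted over the list alone (adjusted p = 1.12e-08, and adjusted p = 0.0222 with an estimated correlation). Ccl2 and Ccl7, for chemokines that draw monocytes, rose 2.70-fold and 2.06-fold, Timp1, for a protease inhibitor, 2.51-fold, and the adhesion gene Icam1 1.59-fold.

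**Figure D3:**
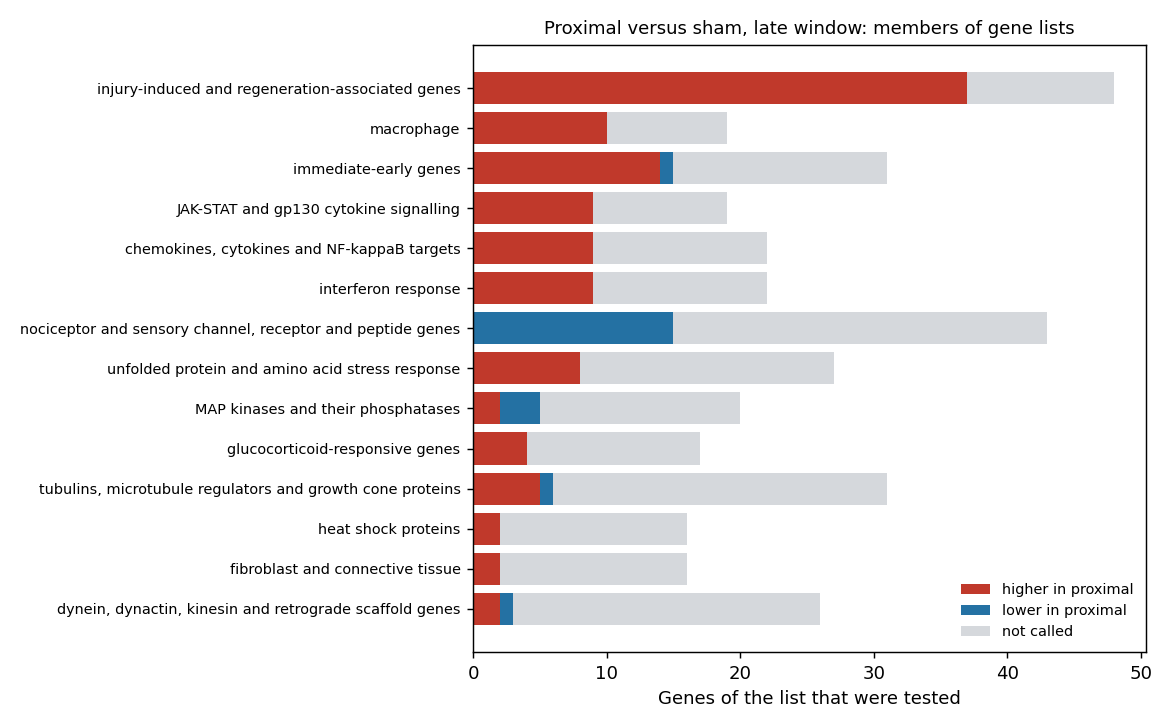
Bars give the number of tested genes of 14 lists (horizontal) that were higher, lower or not called in proximal against sham arrays of the late window, 9 arrays each. The injury-induced list has 37 of 48 genes higher and 0 lower, and the nociceptor list 15 of 43 lower and 0 higher.

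A part of the nociceptor genes fell while a part of the macrophage genes rose, and these list calls were lost with an estimated correlation. Of 43 genes in the list of nociceptor and sensory channels, receptors and peptides, 15 were lower, 0 higher and 28 not called. The list had 16 lower when adjusted over the list alone and a median of -0.18 (adjusted p = 3.26e-08, and adjusted p = 0.298 with an estimated correlation). The glutamate receptor gene Grik1 fell by 0.71 on the log2 scale (SE 0.11), the neurotrophic factor receptor gene Gfra2 by 0.42 (SE 0.07), the heat-gated channel gene Trpv1 by 0.41 (SE 0.08) and the sodium channel gene Scn10a by 0.25 (SE 0.07). The Scn10a call was lost when only the arrays compared were fitted and when all sham arrays were pooled. Macrophage markers had 10 of 19 genes higher, 0 lower and 9 not called, and 11 higher when adjusted over the list alone (adjusted p = 1.59e-08, and adjusted p = 0.273 with an estimated correlation). They included the immune receptor adaptor genes Fcer1g (log2 0.73, SE 0.13) and Tyrobp (0.60, SE 0.13), the Fc receptor gene Fcgr1a (0.60, SE 0.12) and Aif1 (0.86, SE 0.18), of which a dimmer probe set gave -0.022. Satellite glia markers had 1 of 11 genes higher, the same when adjusted over the list alone, 0 lower and 10 not called (adjusted p = 0.00668, and adjusted p = 0.918 with an estimated correlation). That gene was Gfap, an intermediate filament gene of activated glia, which rose 4.39-fold (log2 2.13, SE 0.14, adjusted p = 1.34e-18).

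The interferon response list had 9 of 22 genes higher, 0 lower and 13 not called, and 12 higher when adjusted over the list alone (adjusted p = 1.59e-08, and adjusted p = 0.673 with an estimated correlation). Its members varied between proximal arrays: the GTPase gene Gbp2 rose 2.74-fold with an SD of 1.18 (n = 9), and the immunoproteasome genes Psmb8 and Psmb9 rose 1.90-fold and 1.92-fold with SDs of 0.88 and 1.05 (n = 9). The transcription factor gene Irf1 rose 1.74-fold. The unfolded protein and amino acid stress list had 8 of 27 genes higher, 0 lower and 19 not called, and 10 higher when adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.673 with an estimated correlation). They included Ppp1r15a (log2 0.58), Trib3 (1.53-fold), Chac1 (1.28-fold) and the amino acid transporter gene Slc3a2 (1.25-fold). Glucocorticoid-responsive genes had 4 of 17 higher, 0 lower and 13 not called, and 6 higher when adjusted over the list alone (adjusted p = 0.000544, and adjusted p = 0.991 with an estimated correlation). Those 4 included Cebpd (2.28-fold), which cytokines also induce, the cell cycle inhibitor gene Cdkn1a (1.85-fold), the metallothionein gene Mt2A (1.87-fold) and the phosphatase gene Dusp1 (1.55-fold). Cytosolic ribosomal proteins shifted upwards as a list with 0 of 18 genes called by limma, and 0 when adjusted over the list alone (Rpl11, log2 0.19, SE 0.07, adjusted p = 0.108). Fibroblast and connective tissue markers did so with 2 of 16 higher and 0 lower. The adjusted p was 0.0293 and 0.0253, and adjusted p = 0.991 for both with an estimated correlation. The 2 fibroblast list genes, also 2 when adjusted over the list alone, were Fn1 for fibronectin (log2 0.41) and Postn for periostin (0.57), and Postn was not called without the 18 h arrays.

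Other lists did not shift as a whole in this comparison. Tubulins, microtubule regulators and growth cone proteins had 5 of 31 genes higher and 1 lower, with a median of -0.012, a mean of 0.085 and an upward test direction. Among them Stmn4, for a stathmin family protein that destabilises microtubules, rose 2.82-fold (log2 1.49, SE 0.12), the tubulin gene Tubb6 2.39-fold (log2 1.26, SE 0.13) and the microtubule-associated kinase gene Dclk1 1.43-fold. Importins and nuclear transport genes had 1 of 23 higher, Ipo5 (log2 0.49, SE 0.10), and 1 lower, Ipo9, which fell by 0.21 (SE 0.07, adjusted p = 0.0338) and was not called after another quantile normalization. Kpnb1, for importin beta, differed by 0.16 (SE 0.22, adjusted p = 0.793). Dynein, dynactin, kinesin and scaffold genes had 2 of 26 higher and 1 lower, and 3 higher and 2 lower when adjusted over the list alone. They included the kinesin gene Kif3b (log2 0.24, adjusted p = 0.0369), Vim for vimentin (0.16, adjusted p = 0.0285) and the dynactin gene Dctn1 (-0.29, adjusted p = 0.0115). The calls of Vim, Pcna, Ccne1 and Msmo1 were lost when only the arrays compared were fitted, those of Fn1, Dctn1 and Dusp5 when all sham arrays were pooled, and that of Kif3b without the 18 h arrays. Leaving out single arrays also ended the calls of Vim, Pcna, Ccne1, Kif3b, Ipo9 and Scn10a. At least 1 dimmer probe set each of Ipo5, Kif3b, Tubb6, Dclk1, Stat3, Cebpd, Gap43, Gfra2, Trpv1, Rbfox3 and Smad9 was not called, judged by its unadjusted p. MAP kinases and their phosphatases had 2 of 20 higher, Mapk6 among them (log2 0.41), and 3 lower, Dusp5 (-0.50) and Map3k12 (-0.29) among them.

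Heat shock proteins had 2 of 16 genes higher, Hspb8 (log2 0.32) and Hspb1 (0.37), and 0 lower. Circadian clock genes had 1 of 16 higher, Nfil3 (log2 1.40, SE 0.13, adjusted p = 1.46e-12). Cholesterol biosynthesis had 1 of 19 higher, Msmo1 (log2 0.21), and 4 when adjusted over the list alone. The cell cycle list had 1 of 21 higher, Pcna (0.28, adjusted p = 0.0438), and 1 lower, Ccne1 (-0.28, adjusted p = 0.042). Oxidative phosphorylation had 0 of 24 called. Sensory neuron markers had 1 of 19 lower, the neuronal splicing factor gene Rbfox3, which fell by 0.65 (SE 0.12), and 2 lower when adjusted over the list alone. Myelinating Schwann cell markers had 0 of 11 called, with a median of -0.0089 and a mean of 0.017. Lymphocyte markers had 0 of 8 called, erythrocyte markers 0 of 5, endothelial markers 0 of 14 and pericyte and smooth muscle markers 0 of 9, the last with 1 lower when adjusted over the list alone. Skeletal muscle markers had 0 of 13 called and a median of -0.40, with Acta1 at -0.45 (SE 0.53) and Ckm at -0.41 (SE 0.55). Too few genes were left for a list test of adipocyte markers (0 of 3 called), spinal cord markers (0 of 3) and neutrophil markers, of which 1 of 3, the granulocyte gene S100a9, was higher (log2 0.97, SE 0.21, adjusted p = 0.000676). S100a9 was at 8.95 and 9.30 in proximal 28 h b and c, while the other 7 proximal arrays lay between 5.73 and 6.67 and the sham arrays between 5.44 and 6.47.

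Hour by hour after the proximal lesion, Atf3, Sox11, Gadd45a and Il6 were called at 18, 24 and 28 h, and Stat3 at 8 and 18 h. Stat3 rose by 0.47 at 18 h (adjusted p = 0.00578) and was not called at 24 h (adjusted p = 0.541) or 28 h (adjusted p = 0.26). Npy and Gap43 were called at 28 h alone, and Sprr1a and Egr1 at no hour. At 8 h Stat3 was higher by 0.41 (SE 0.11, adjusted p = 0.028, 3 arrays each), a call that was lost after another quantile normalization, with all sham arrays pooled and without any of 5 of the 6 arrays. Socs3 (0.57, SE 0.20, adjusted p = 0.127), Atf3 (1.06, SE 0.51, adjusted p = 0.364), Jun (0.36, adjusted p = 0.628), Gadd45a (0.30, adjusted p = 0.846), Fos (0.72, adjusted p = 0.61) and Il6 (-0.36, adjusted p = 0.843) were not called. These SEs pool the spread of all groups, among them sham 12 h with Atf3 at 7.32 and 11.55, so a missing call does not exclude a rise. In Atf3 (7.26 or more against 6.62 at most), Socs3, Jun and Fos all 3 proximal arrays of 8 h lay above all 3 sham arrays. In Gadd45a and Il6 the arrays of 8 h overlapped. Atf3 rose by 3.89 at 18 h, 3.15 at 24 h and 3.84 at 28 h (SE 0.51 at each). Sox11 rose by 2.39, 2.33 and 2.34 (SE 0.33), Gadd45a by 2.20, 2.33 and 2.53 (SE 0.33), and Il6 by 3.86, 3.44 and 3.07 (SE 0.39). S100a9 was called at 28 h (2.64, adjusted p = 4.53e-07). Within the technical sets at 18 h, Atf3 differed by 4.62 in set B (2 arrays each) and 2.42 in set C (1 array each), and Il6 by 4.70 and 2.20. When only the 18 h arrays compared were fitted, Atf3 and Il6 were not called. The hours of 12 and 16 h had 1 or 2 arrays in a group, among them the array labelled sham 12 h b, which exceeded the 19 other sham arrays in all 10 genes with the largest late rises. Sham 16 h a did so in 6 of them, without Atf3, Il6, Vip and Gadd45a. With 1 array each, Atf3 differed at 12 h by 3.26 and Gadd45a by 2.66 in set C, and by -0.088 and -0.28 in set B, which holds sham 12 h b. The sham array of set C, sham 12 h a, had the largest differences between 3' and 5' control probe sets of all 72 arrays (2.58 log2 for actin and 1.59 for gapdh) and less Gadd45a (7.93) than any other sham array (9.33 or more). At 16 h in set B Atf3 differed by 1.78 and Sox11 by 1.46.

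Genes called by limma numbered 0 at 1 h (247 at unadjusted p under 0.05), 0 at 3 h (307 unadjusted), 215 at 8 h, 4 at 12 h, 6 at 16 h, 185 at 18 h, 148 at 24 h and 549 at 28 h. With technical set as a block they numbered 1, 5, 942, 36, 32, 779, 410 and 1099, and with the array letter as a block within 1 h and 18 h 319 were called at 18 h. At 8 h all proximal and sham arrays lay in set C, so the block left the differences unchanged and moved the count through the estimate of the spread alone. Of the 215 genes at 8 h 204 were higher, a split that another quantile normalization moved to 157 of 224, and without the array sham 8 h c only 4 genes were called and Stat3 was not. Without sham 12 h b 523 genes were called at 12 h, and without proximal 16 h b 736 at 16 h. The splits also moved at 12 h (4 of 4 higher against 15 of 18), 16 h (3 of 6 against 17 of 21), 18 h (150 of 185 against 263 of 407) and 24 h (119 of 148 against 169 of 262). At 28 h 378 genes were higher and 171 lower. A set of 96 genes was called at 18, 24 and 28 h with one sign, 86 higher and 10 lower.

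**Figure D4:**
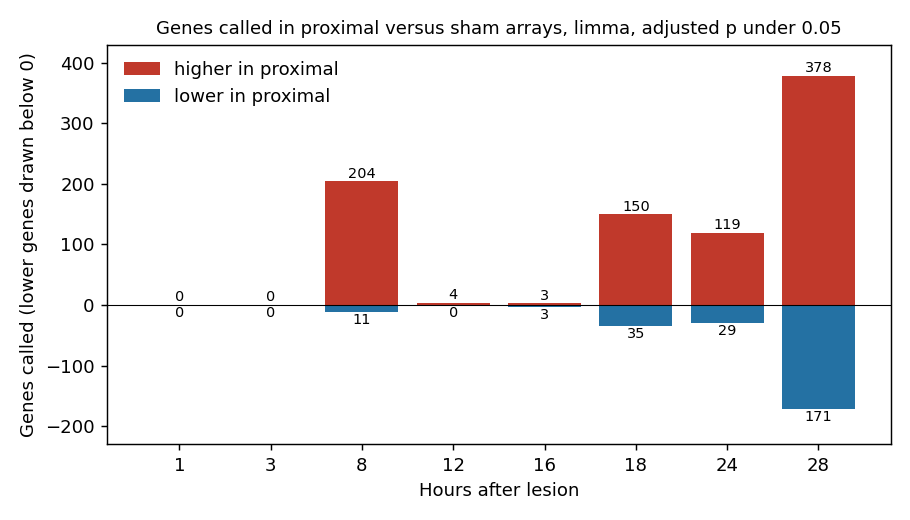
Bars give the number of genes called by limma at adjusted p under 0.05 in proximal against sham arrays (vertical, lower genes drawn below 0) at each hour after the lesion (horizontal), with 3 arrays per group except 2 and 2 at 12 h and 2 and 1 at 16 h. Counts were 204 higher and 11 lower at 8 h, and 378 higher and 171 lower at 28 h.

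In the early window few genes differed between proximal and sham arrays. Pfkl, for an enzyme of glycolysis, was 1.58-fold higher (log2 0.66, SE 0.14, adjusted p = 0.0303, higher in 8 of 9 arrays), the secreted glial protein gene Lgi4 1.33-fold (0.41, SE 0.09, adjusted p = 0.0303), and the actin-binding protein gene Pfn1 1.34-fold (0.42, SE 0.09, adjusted p = 0.0343). Cnpy3 (0.44, SE 0.10) and Gbf1 (0.42, SE 0.09), a gene of Golgi trafficking, were also higher at the same adjusted p, and Cbx1, for a heterochromatin protein (-0.59, SE 0.13), and Rlig1 (-0.37, SE 0.08) were the 2 genes that were lower. Dimmer probe sets of Gbf1 and Cbx1 gave the opposite sign. Each of these 7 calls ended when single arrays were left out, and 6 of them, all but that of Cbx1, when all sham arrays were pooled. Genes of injured neurons were not called. Atf3 differed by 0.58 (SE 0.30, adjusted p = 0.456), Fos by 0.50 (SE 0.28), Egr1 by 0.33, Junb by 0.37 (SE 0.11, adjusted p = 0.119), Nr4a1 by 0.25 and Ccl2 by 0.40. Stat3 differed by 0.24 (SE 0.06, adjusted p = 0.0605), Sox11 by 0.13, Gadd45a by 0.12, Jun by 0.055 and Il6 by -0.17. Lists of interferon response (0 of 22 genes called), fibroblast markers (0 of 16) and skeletal muscle markers (0 of 13) shifted downwards and oxidative phosphorylation (0 of 24) upwards at adjusted p = 0.00369, 0.0238, 0.0428 and 0.0499, and 0 of the 4 held with an estimated correlation. limma called 16 genes (14 higher and 2 lower), 166 after another quantile normalization (121 higher and 45 lower) and 588 with technical set as a block, when Stat3, Junb and Nr4a1 were also called. With the array letter as a block within 1 h and 18 h 105 genes and 2 lists were called, and Stat3 was among the genes (0.24, adjusted p = 0.0395). The count fell to 1 without proximal 3 h b and reached 187 without sham 1 h a.

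After the distal lesion, the late window showed many of the same named genes at high levels. Flrt3 was 15.1-fold higher than after sham (log2 3.91, SE 0.18, adjusted p = 9.42e-24) and Atf3 10.1-fold (log2 3.33, SE 0.28, adjusted p = 2.97e-14). Il6 was at least 7.47-fold higher (log2 4.15, SE 0.22, adjusted p = 5.73e-22) and Vip at least 3.63-fold (log2 2.37, SE 0.12), with sham means of 4.43 and 5.39 below the filter level. Fos rose 5.01-fold (log2 2.33, SE 0.27). Gadd45a rose 4.93-fold, Sox11 3.52-fold and Adcyap1 3.07-fold, while Racgap1 fell by 1.39 on the log2 scale (SE 0.10) and Gfra2 by 0.90 (SE 0.07). All 12 distal arrays were apart from all 9 sham arrays in 8 of these genes: Il6, Flrt3, Atf3, Adcyap1, Sox11 and Gadd45a lay above and Racgap1 and Gfra2 below. With technical set as a random block these 10 genes were still called, with Il6 at 3.57 (adjusted p = 0.000607), Atf3 at 3.44 (adjusted p = 0.0249) and Sox11 at 1.70 (adjusted p = 0.036).

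Genes with other late differences from sham were called only without that block. The cadherin gene Cdh22 was 27.3-fold higher (log2 4.77, SE 0.49) with an SD of 1.40 among sham arrays, although a dimmer probe set gave -0.16. The signalling gene Rasal2 was at least 23.3-fold higher, with a sham mean of 5.33 below the filter level, Tcf4 for a neural transcription factor 17.8-fold, Onecut2 16.3-fold and the neurotrophin receptor gene Ntrk3 7.62-fold. Tlx3, a transcription factor gene of sensory neurons (log2 -1.84), the phosphatase subunit gene Ppp2r2c (-1.65), Nf1 for the Ras regulator neurofibromin (-1.54), the potassium channel gene Kcnc4 (-0.98) and the channel gene Hcn2 (-0.94) were lower. Gal (log2 1.15, SE 0.09), Jun (1.00, SE 0.13), Socs3 (0.36, SE 0.11) and Stat3 (-0.22, SE 0.06) belonged here too, and a second, dimmer probe set of Stat3 was higher by 1.00 (unadjusted p = 0.00357 by limma). limma called 7590 genes (3971 higher and 3619 lower) without a block and 88 with technical set as a random block.

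Of the lists in the late distal comparison, the injury-induced one had 36 of 48 genes higher, 3 lower and 9 not called (adjusted p = 1.63e-14, and adjusted p = 0.0329 with an estimated correlation). The nociceptor list had 24 of 43 lower, 7 higher and 12 not called (adjusted p = 0.00399), and ribosomal protein genes 17 of 18 higher (adjusted p = 0.000616), such as Rpl27 (log2 0.43, SE 0.05) and Rpl19 (0.33, SE 0.05). Glucocorticoid-responsive genes had 11 of 17 higher and 1 lower (adjusted p = 0.0141), unfolded protein genes 16 of 27 higher and 2 lower (adjusted p = 0.0487) and lymphocyte markers 6 of 8 lower and 0 higher (adjusted p = 0.0287). For those 5 lists the adjusted p was 0.991 with an estimated correlation. Above the median level of all genes lie 17 of 18 ribosomal, 15 of 17 glucocorticoid-responsive and 21 of 27 unfolded protein genes, and 0 of 8 lymphocyte markers. Of the nociceptor genes, a list that was lower, 30 of 43 do. A part of these list differences due to technical set cannot be told apart from the lesion.

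In the early window distal arrays differed from sham arrays in most genes. Bdnf, for a neurotrophin, was 2.92-fold higher (log2 1.55, SE 0.19, adjusted p = 5.25e-09), Ccl2 2.20-fold (1.14, SE 0.16), Fos 2.97-fold (1.57, SE 0.26), and Gadd45b 1.84-fold (0.88, SE 0.14). Ier3 was 1.78-fold higher (0.83, SE 0.12) and Atf3 1.92-fold (0.94, SE 0.28, adjusted p = 0.00287). The largest differences included Rpl37-ps2, at least 3.06-fold higher (1.81, SE 0.17, sham mean 5.34 below the filter level), the ribosome assembly kinase gene Riok2 (1.79, SE 0.21), Slbp for a histone messenger binding protein (1.75, SE 0.18), Ly6al (-2.00, SE 0.39) and Terf2 for a telomere protein (-1.75, SE 0.23). Cxcr2, for a chemokine receptor of neutrophils, was at least 1.33-fold lower (-0.72, SE 0.11, distal mean 5.14). None of these 12 genes was called by limma with technical set as a random block, where Ly6al turned to 0.33. Other probe sets of Bdnf, Fos, Slbp and Terf2 gave the opposite sign. Pooling all sham arrays turned Atf3 to -0.33 (adjusted p = 0.405). The lists of chemokines (2 of 22 higher, 11 lower and 9 not called) and of lymphocyte markers (0 of 8 higher, 7 lower) shifted downwards (adjusted p = 0.00171 and 9.62e-05, and adjusted p = 0.418 and 0.298 with an estimated correlation). Of their genes only 4 of 22 and 0 of 8 lie above the median level of all genes, and technical set cannot be told apart from the lesion here.

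The number of genes called between distal and sham arrays was 8436 in the early window (5971 higher and 2465 lower) and 0 with technical set as a random block (1142 at unadjusted p under 0.05). Another quantile normalization shifted the median of all genes by -0.20 log2 in this comparison and left 3581 of 7439 genes higher. By hour limma called 4564 genes at 1 h, 5309 at 3 h, 7222 at 8 h, 2128 at 12 h, 13 at 16 h, 1427 at 18 h, 4672 at 24 h and 5205 at 28 h. With technical set as a fixed block, which could be fitted at 5 of these hours, 242 were called at 3 h, 80 at 8 h, 0 at 12 h (1329 unadjusted), 3 at 16 h and 387 at 18 h. Of these, 51, 30, 0, 3 and 256 were also called without the block in the same direction. The share of higher genes went from 48.3% to 38% at 1 h after another quantile normalization, from 69.6% to 47.4% at 3 h and from 79.7% to 56.3% at 8 h. It went from 77.3% to 46.9% at 12 h, from 61.5% to 83.3% at 16 h, from 52.8% to 38% at 24 h and from 56.1% to 44.5% at 28 h. The shift of the median was -0.22 at 3 h, -0.27 at 8 h, -0.16 at 12 h, -0.14 at 24 h and -0.11 at 28 h, and in the proximal comparison at 16 h it was 0.16.

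Set against each other in the late window, proximal arrays had more Stat3 (log2 0.53, SE 0.06, adjusted p = 1.67e-10, above all 12 distal arrays in 9 of 9), Socs3 (0.73, SE 0.11), Cish (0.58, SE 0.10), and Bcl3, a gene of NF-kappaB regulation (0.59, SE 0.07). Ecel1, for a neuronal endopeptidase (0.61, SE 0.08), and Sox11 were also higher (Sox11 0.54, SE 0.18, adjusted p = 0.0111), and Il6 was lower (-0.69, SE 0.22, adjusted p = 0.0066). S100a9 was higher as well (0.94, SE 0.20), with the arrays proximal 28 h b and c apart, since distal arrays lay between 5.40 and 6.36 and the other 7 proximal arrays reached 6.67. Atf3 (0.29, SE 0.28, adjusted p = 0.394), Gal (-0.0056, SE 0.09, adjusted p = 0.961) and Gadd45a (0.05, SE 0.18, adjusted p = 0.821) were not called. The second probe set of Stat3 went the other way (-0.69, unadjusted p = 0.0399 by limma), as did another of Cdh22 (0.13). Rasal2 was at least 23.3-fold lower in proximal arrays (log2 -4.76) and Onecut2 at least 17.2-fold (-4.18), with proximal means of 5.26 and 5.33 below the filter level. Cdh22 (-4.67), the calcium channel subunit gene Cacna2d1 (-2.95), Ntrk3 (-2.89) and Rpl27 (-0.35) were lower and Ppp2r2c (1.66) and Nf1 (1.52) higher in proximal arrays. None of the genes named here was called by limma with technical set as a random block.

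Several lists differed between the sites in the late window, 0 of them with an estimated correlation. Higher lists were immediate-early genes (13 of 31 higher in proximal arrays and 2 lower, adjusted p = 0.0262), JAK-STAT genes (9 of 19 higher and 3 lower, adjusted p = 0.0487) and chemokines (13 of 22 higher and 2 lower, adjusted p = 0.0124). So were interferon response genes (7 of 22 higher and 0 lower, adjusted p = 0.0499) and lymphocyte markers (7 of 8 higher, adjusted p = 0.00388). Ribosomal protein genes stood lower (12 of 18 lower and 0 higher, adjusted p = 0.00974). In the higher lists, in the order given, 10 of 31, 6 of 19, 4 of 22, 7 of 22 and 0 of 8 genes lie above the median level of all genes. Of the ribosomal protein genes 17 of 18 do. Arrays of set A, all distal, had a wider interquartile range than those of sets C and D. These list differences therefore cannot be told apart from technical set. limma called 6553 genes (3043 higher and 3510 lower) and 2 with technical set as a random block. Another quantile normalization moved the share of higher genes from 46.4% to 56.4%.

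In the middle window Stat3 was again higher in proximal than in distal arrays (0.49, SE 0.09, adjusted p = 0.000207, 4 arrays against 5). The kinase gene Camk2a (1.5, SE 0.37), Adam3a (1.41, SE 0.35) and Scn10a (0.37, SE 0.10) were higher too. Lower genes were Gap43 (-0.35, SE 0.08), Fos (-1.19, SE 0.40, adjusted p = 0.0197), Cdh22 (-1.94), the mitochondrial enzyme genes Acadsb (-1.93) and Nars2 (-1.85), and Rpl27 (-0.42). Il6 was at least 1.27-fold lower (log2 -1.03, SE 0.33, adjusted p = 0.0142), with a proximal mean of 5.18 below the filter level. That rested on 16 h, with 5.96 and 5.47 in proximal and 7.94 and 8.41 in distal arrays, while at 12 h all 5 arrays lay below that level. Other probe sets gave the opposite sign for Camk2a (-0.54), Fos (0.24), Gap43 (0.023) and Cdh22 (0.16). Atf3 (0.53, SE 0.43), Sox11 (0.30, SE 0.27) and Gadd45a (-0.24, SE 0.27) were not called. Ribosomal protein genes (11 of 18 lower, adjusted p = 0.00213) and oxidative phosphorylation genes (11 of 24 lower and 1 higher, adjusted p = 0.0287) stood lower. Lymphocyte markers (5 of 8 higher and 1 lower, adjusted p = 0.0145) stood higher, and 0 of the 3 lists were called with an estimated correlation. Above the median level of all genes lie 17 of 18, 24 of 24 and 0 of 8 genes of these lists. Technical set cannot be told apart from lesion site here. limma called 4274 genes (1328 higher and 2946 lower), with 2273 of 4148 higher after another quantile normalization, which shifted the median by 0.13. The count was 0 by limma with technical set as a fixed block (811 at unadjusted p under 0.05), when Cdh22 turned to 0.90. In the early window 7989 genes differed between the sites (2933 higher in proximal arrays and 5056 lower). After another quantile normalization, which shifted the median by 0.16, 4385 of 7757 were higher, and 47 were called with technical set as a random block.

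The difference between lesion and sham changed from the early to the late window in 1064 genes for the proximal lesion, 372 with a larger and 692 with a smaller value late (2544 with technical set as a block). For the distal lesion it changed in 3677 genes, 885 larger and 2792 smaller (1236 with the random block). For the distal lesion another quantile normalization moved the share with a larger value from 24.1% to 41.5%. Among the 21 sham arrays 6577 genes differed between hours, which fell into different technical sets, and 2017 with the random block. Within technical set D, which held the sham arrays of 1, 24 and 28 h, 105 genes changed with time (9 arrays), and within set C 0 genes differed between 3 and 8 h by limma (501 at unadjusted p under 0.05, 6 arrays).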

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

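The grouping of splits by letter pairs and the tests of technical set, of the arrays labelled sham 12 h b and 16 h a of time after surgery and of muscle RNA were chosen after the results were seen, as was the late against early comparison of distal arrays, and the counts over other splits of the arrays were planned.

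Large numbers of genes differed between distal and sham arrays even at 1 h (4564) and 8 h (7222). Technical set may account for them: across genes, the difference between 5 distal arrays of set A and the 1 distal array of set C at 18 h, which share a lesion and an hour, correlated with the distal minus sham difference at 3 and 8 h (r = 0.812 across genes, which are not independent replicates). With technical set as a block 80 genes were called at 8 h, 30 of them also among the 7222 in the same direction, while the SD of the log2 differences went from 0.51 to 0.30 and the standard errors grew 1.22-fold, so the calls ended mainly because the differences shrank. That block rests on 2 distal arrays outside set A, and the distal 18 h array in set C had a response score of 0.263 against 0.989 to 1.19 in the other 5 distal 18 h arrays, so a part of the early distal difference due to the lesion cannot be told apart from technical set. Technical set cannot be the whole cause of the late rise of Atf3 and Il6, which was 4.6 and 4.63 from early to late distal arrays within set A and stayed called with the random block (3.44 and 3.57 against sham), nor can time after surgery as in the sham arrays of set D, whose rise from 1 h to 24 and 28 h (1.5 and 0.13) the distal rise exceeded by 3.29 (SE 0.53) and 4.63 (SE 0.20).

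Of the 10 genes with the largest late proximal rises, the array labelled sham 12 h b exceeded the 19 other sham arrays in 10 and sham 16 h a in 6, such as Sox11 (6.64 against 5.74 at most) and Flrt3 (9.46 against 8.62), but not in Atf3 (9.97 against 10.16), Il6, Vip and Gadd45a. A response score, the mean rise of 91 genes that rose by at least 1 log2 within set D after the proximal lesion, was 0.849 and 0.524 in them, from -0.247 to 0.373 in the other 19 sham arrays and from 0.108 to 0.743 in the 4 proximal arrays of 12 and 16 h. A wrong sample label may account for sham 12 h b, whose score exceeded the lowest of those proximal arrays by 0.741, while proximal 12 h a (0.108) and distal 18 h do (0.263), which scored within the range of the other sham arrays, carried more Atf3 (10.58 and 10.99) than any of these (10.16 at most). The score of sham 12 h b and its Il6 (7.07 against 5.96 at most) lay above those of all 4 proximal arrays, however. Those 4 exceeded the 19 other sham arrays in 4, 6, 8 and 8 of the 10 genes, so a wrong label of sham 12 h b is not shown. For sham 16 h a, whose score exceeded that lowest score by 0.415, a wrong label stays open, since its Atf3 was below that of the 4 proximal arrays (10.58 at least). Technical set as the cause stays open: the lower of the 2 scores exceeded the highest of the other sham arrays of set B by 0.380, but set B has only 2 of these, both of 18 h, and a response of these animals to the sham surgery was not tested.

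Skeletal muscle genes were high in some arrays. The 8 arrays with the most Acta1 were distal 8 h c (12.64), distal 18 h a, b and c (12.04, 11.84 and 12.05), distal 16 h b (11.79), sham 18 h b (11.69), proximal 12 h a (11.44) and proximal 3 h a (10.88), against a median of 8.93 over all arrays, and 11 of the 12 other tested muscle markers lay above their own median in all 8. RNA of skeletal muscle cells in the dissected tissue may account for this. Muscle genes raised by the proximal lesion stay open for proximal 3 h a and 12 h a: 0 of 13 markers were called higher by limma at these hours (0 at unadjusted p under 0.05, medians of 0.45 and 1.36), with 2 or 3 arrays a group. The list shares 0 genes with the other lists and 2 of its 13 genes lie above the median level of all genes, while Myh1, from 10.2 to 12.1, was bright in all 72 arrays.

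Single arrays stood apart from the rest of their group for 5 of 50 combinations of gene and group that were tested, where chance gives about 1 in 20. Bdnf was 8.88 in distal 8 h b and 9.19 to 9.30 in the other 4 arrays of its group. Cxcr2 was 4.55 in distal 8 h eo and 5.04 to 5.21 in the others. In distal 18 h do, the array in set C, Nf1 was 7.12 against 5.40 to 5.54, Jun 10.37 against 11.26 to 11.49 and Rpl27 12.66 against 12.98 to 13.13. The change from the early to the late window differed between lesion and sham in 1064 genes for the proximal and 3677 genes for the distal lesion. Among 6150 probe sets without a single gene name, which the comparisons leave out, 319 were called in proximal against sham arrays of the late window (185 higher and 134 lower). The probe set for the dap spike-in RNA, added to samples as a control, had a mean of 11.1 in the 6 distal arrays whose letter is followed by o, 3.70 ± 0.23 (SD) in the other 23 distal arrays, 10.06 ± 1.72 (SD) in 21 sham arrays and 9.59 ± 1.53 (SD) in 22 proximal arrays.

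Other splits of the same arrays into groups of the same sizes were counted for each comparison. For proximal against sham in the late window 1 of 100 splits, the real one, gave as many genes (1192, and 400 at most in another). In the early window 4 of 100 did (16 genes, and 729 at most in another, the split that exchanges proximal 1 h c and sham 1 h a). A split with many times the real count points to a structure of the samples. These splits ignore the pairing by letter found at 1 h, and the real count fell to 1 without proximal 3 h b. Chance is therefore not excluded for the early count. The proximal late minus early count was also highest (1 of 100, 1064 and 306 at most). Both late tests ignore pairing too, so chance is not excluded. The real split gave the most genes for distal against sham early (1 of 100, 8436 and 6980 at most) and late (1 of 100, 7590 and 4808). The same was seen for proximal against distal early (1 of 100, 7989 and 4464), middle (1 of 60, 4274 and 2716) and late (1 of 100, 6553 and 4569). It was seen for distal against sham at 1 h (1 of 35, 4564 and 3059) and 8 h (1 of 56, 7222 and 1034). So it was for the late minus early difference of the distal lesion (1 of 100, 3677 and 3548) and for time within sham (1 of 100, 6577 and 5071). Set A held only distal arrays and sham hours fell into different sets, so the real split of these comparisons follows technical set. Other splits mix the sets, so these counts cannot part lesion or time from technical set.

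Splits were too few for a share under 0.05 for proximal against sham at 1 h (real count 0, highest other 85), 3 h (0 and 0), 8 h (215 and 0), 18 h (185 and 2606), 24 h (148 and 72) and 28 h (549 and 55), with 10, 10, 1, 4, 1 and 1 of 10 splits as large. They were also too few for distal against sham at 3 h (5309 and 0), 24 h (4672 and 0) and 28 h (5205 and 0), with 1 of 10 each. At 18 h the split with 2606 genes exchanges proximal c and sham b and follows technical sets B and C, and with technical set as a block the real count was 779. The letters pair proximal and sham arrays at 1 h and 18 h. Of the 10 splits there, 4 part all 3 pairs, the real one included, and the highest other of these was 0 at both hours, while the 6 that part 1 pair reached 85 at 1 h and 2606 at 18 h. For distal against sham at 18 h 8 of 84 splits were as large (1427, and 5830 at most), so chance is not excluded there. The largest of those splits exchanges distal do and fo with sham a and b, and the blocked count was 387. For lists, 2 of 100 splits gave at least 12 in proximal against sham late (12 at most and 6 at the median in the others). Another split gave as many and the splits ignore pairing, so chance is not excluded for that count or any single list. It is not excluded for proximal against sham early (36 of 100, 4 and 8 at most), distal against sham early (83 of 100, 2 and 12) and late (26 of 100, 6 and 9), or proximal against distal middle (59 of 60, 3 and 8) and late (23 of 100, 6 and 10).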

How the results depend on the processing

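Technical set as a block, the letter as a block within 1 h and 18 h, the fits without the arrays labelled sham 12 h b and sham 16 h a, the late window without 18 h and the comparison of late with early distal arrays, with its covariates for RNA quality, were chosen after the results were seen, and the other alternatives were planned. Of the 82 called genes named in the report for proximal against sham in the late window, 69 were called in the same direction under every alternative except other probe sets of the gene. Atf3 there ran from 3.48 to 4.37, Il6 from 3.25 to 3.80 and Sox11 from 2.29 to 2.48, with adjusted p up to 9.16e-07, 1.6e-08 and 3.31e-09. For distal against sham in the late window the same held for 10 of 26 genes. Signal near background limits dim genes. The filter takes the mean over all arrays, so that genes dim in 1 group, such as Il6, Vip and Rasal2 in sham arrays, were tested. The shifts of counts below follow in part from how an alternative is built (fewer genes, fewer arrays, more probe sets, or a block in the fit), and otherwise the cause was not tested.

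Counts of genes called that moved by more than 1.5 times, by limma, were these. Without the filter on dim probe sets, proximal against sham gave 13 at 16 h. Called lists were 5 in the early window for distal against sham and 5 in the middle window for proximal against distal. With the stricter filter, proximal against sham gave 44 in the early window, 0 at 12 h (584 at unadjusted p under 0.05, given below as unadjusted) and 2 at 16 h. Distal against sham had 7 at 16 h. Of the lists, 2 in the early window for proximal against sham, 3 in the late window for distal against sham and 1 in the late window for proximal against distal were called. After another quantile normalization, proximal against sham gave 166 in the early window, 1803 in the late window, 1 at 1 h, 4 at 3 h, 18 at 12 h, 21 at 16 h, 407 at 18 h and 262 at 24 h. Distal against sham came to 4662 at 8 h and 2187 at 18 h and the late minus early difference gave 1819 for the proximal lesion. The lists called were 2 in the early window for proximal against sham, 1 in the early window for distal against sham and 2 in the late window for proximal against distal. With array weights, proximal against sham gave 2087 in the early window, 3429 in the late window, 1142 at 1 h, 288 at 3 h, 1396 at 8 h, 0 at 12 h (11 unadjusted), 0 at 16 h (955 unadjusted), 1260 at 18 h, 1069 at 24 h and 4388 at 28 h. Distal against sham gave 8612 at 1 h, 8578 at 3 h, 0 at 12 h (1474 unadjusted), 1345 at 16 h, 4974 at 18 h, 8024 at 24 h and 9465 at 28 h. The late minus early difference gave 3983 for the proximal lesion and 7650 for the distal lesion. Proximal against distal had 1111 in the middle window and time within sham gave 11803. Called lists were 1 in the early window for proximal against sham. The array weights ran from 7.79e-07 for proximal 18 h a to 44 for sham 1 h b, so counts with weights can rest largely on single arrays. Without the arrays whose letter is followed by o, proximal against sham gave 157 in the early window, 418 at 8 h, 12 at 12 h, 29 at 16 h and 294 at 18 h. Distal against sham came to 40 at 16 h and 2377 at 18 h. With every probe set counted, proximal against sham gave 8 in the early window, 55 at 12 h and 3 at 16 h. Distal against sham gave 15596 in the early window, 14304 in the late window, 8278 at 1 h, 9750 at 3 h, 12076 at 8 h, 4406 at 12 h, 24 at 16 h, 3417 at 18 h, 8670 at 24 h and 9774 at 28 h. Proximal against distal had 15008 in the early window, 7700 in the middle window and 12772 in the late window. The late minus early difference gave 7303 for the distal lesion and time within sham gave 12460. With the array letter as a replicate block, proximal against sham gave 107 in the early window, 14 at 12 h and 22 at 16 h. Distal against sham came to 35 at 16 h. The block changed no other count by that much. Over all hours the letters were not taken to pair arrays, since deviations from the group means correlated above 0.1 in 12 of 20 pairs of proximal and sham arrays with one letter and time (lowest -0.31, median 0.29), in 3 of 20 pairs of distal and sham arrays and in 6 of 21 pairs of proximal and distal arrays. At 1 h and 18 h all 3 pairs of proximal and sham arrays did. With the letter as a replicate block within these hours, proximal against sham gave 105 in the early window, 319 at 18 h and 0 at 1 h (413 unadjusted), and 2 lists in the early window. It brought Stat3 in the early window past the threshold (0.24, adjusted p = 0.0395) and changed no other call of a named gene.

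With a fixed block for technical set, proximal against sham gave 588 in the early window, 2336 in the late window, 1 at 1 h, 5 at 3 h, 942 at 8 h, 36 at 12 h, 32 at 16 h, 779 at 18 h, 410 at 24 h and 1099 at 28 h. Distal against sham gave 242 at 3 h, 80 at 8 h, 0 at 12 h (1329 unadjusted), 3 at 16 h and 387 at 18 h. Proximal against distal had 0 in the middle window (811 unadjusted) and the late minus early difference gave 2544 for the proximal lesion. Of the lists, 1 in the middle window for proximal against distal was called. With a random block for technical set, proximal against sham gave 549 in the early window, 2277 in the late window, 1 at 1 h, 4 at 3 h, 922 at 8 h, 39 at 12 h, 35 at 16 h, 701 at 18 h, 399 at 24 h and 1068 at 28 h. Distal against sham came to 0 in the early window (1142 unadjusted), 88 in the late window, 0 at 1 h (468 unadjusted), 55 at 3 h, 30 at 8 h, 5 at 12 h, 5 at 16 h, 372 at 18 h, 5 at 24 h and 33 at 28 h. Proximal against distal gave 47 in the early window, 0 in the middle window (872 unadjusted) and 2 in the late window. The late minus early difference gave 2459 for the proximal lesion and 1236 for the distal lesion. Time within sham gave 2017. With only the arrays compared in the fit, proximal against sham gave 62 in the early window, 67 at 3 h, 500 at 8 h, 0 at 12 h (17 unadjusted), 0 at 16 h (156 unadjusted), 3 at 18 h, 90 at 24 h and 1605 at 28 h. Distal against sham had 8093 at 3 h, 0 at 12 h (2284 unadjusted), 1535 at 16 h, 37 at 18 h and 7986 at 28 h. Proximal against distal came to 1680 in the middle window. With all sham arrays pooled, proximal against sham gave 76 in the early window, 1847 in the late window, 1434 at 1 h, 114 at 8 h, 34 at 16 h, 915 at 18 h, 510 at 24 h and 1151 at 28 h. Distal against sham gave 5782 at 12 h, 2383 at 16 h and 4587 at 18 h. The lists called were 4 in the early window for distal against sham. With an estimated correlation, the lists called were 0 in the early window and 4 in the late window for proximal against sham, 0 in the early window and 1 in the late window for distal against sham and 0 in the middle window and 0 in the late window for proximal against distal. Without the arrays labelled sham 12 h b and sham 16 h a, proximal against sham gave 47 in the early window and 523 at 12 h. Distal against sham had 4861 at 12 h. With the o arrays added, late against early distal arrays gave 3503, and with the actin 3' to 5' difference as a covariate 3578. The late window without 18 h moved no count by that much, with 878 genes for proximal against sham, 7392 for distal against sham and 6706 for proximal against distal.

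Leaving out each array in turn moved these counts, which are those of the hour of the arrays named unless a window is given. Proximal against sham ran from 1 without proximal 3 h b to 187 without sham 1 h a in the early window, from 4 without sham 8 h c to 370 without sham 8 h b, from 0 (1190 unadjusted) without proximal 12 h a to 523 without sham 12 h b, from 2 without proximal 16 h a to 736 without proximal 16 h b. The same comparison ran from 97 without proximal 18 h a to 894 without proximal 18 h c, from 83 without proximal 24 h a to 153 without proximal 24 h c, from 270 without proximal 28 h b to 557 without proximal 28 h a. Distal against sham ran from 2905 without sham 1 h c to 4498 without distal 1 h do, from 4632 without sham 8 h a to 6987 without distal 8 h a, from 31 without sham 12 h a to 4862 without sham 12 h b, from 4 without distal 16 h c to 8 without distal 16 h b. The same comparison ran from 711 without sham 18 h b to 2819 without distal 18 h do. Proximal against distal ran from 1579 without proximal 12 h a to 5718 without proximal 12 h b in the middle window. The lists called for proximal against sham ran from 1 without proximal 3 h b to 6 without proximal 1 h a in the early window. Without any 1 array, proximal against sham in the late window stayed between 971 and 1371 genes and between 10 and 13 lists, and distal against sham in the late window between 6985 and 8202 genes.

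Among values of named genes, leaving out 1 array ended the call in 155 of 3873 cases and brought 5 above it. The random block ended 53 of 195 and brought 5 above it, the fixed block 10 and 4 of 138, all sham arrays pooled 15 and 2 of 162, only the arrays compared 14 and 5 of 195, the late window without 18 h 10 and 0 of 162, array weights 6 and 11 of 226 and another quantile normalization 4 and 2 of 226. Each RNA quality covariate and the added o arrays ended 2 of 31. The stricter filter, both letter blocks and the fits without the o arrays or the 2 sham arrays ended 0 and brought 1 above it each. Of 77 values by other probe sets, 16 missed unadjusted p under 0.05 and 22 changed sign at any p. The values that turned were these, and the cause was not tested. Cdh22 in proximal against distal of the middle window went from -1.94 to 0.90 with the fixed block and 0.50 with the random block, Ly6al in distal against sham of the early window from -2.00 to 0.33 with the random block, and Atf3 there from 0.94 to -0.33 with all sham arrays pooled. By another probe set, in proximal against sham of the early window, Cbx1 went from -0.59 to 0.10 and 0.052 and Gbf1 from 0.42 to -0.13 and -0.17. In the late window Aif1 went from 0.86 to -0.022, Dclk1 from 0.52 to -0.0086 and Fos from 1.95 to -0.024. In distal against sham of the early window Bdnf went from 1.55 to -0.15, Fos from 1.57 to -0.039, Slbp from 1.75 to -0.18 and -0.015, and Terf2 from -1.75 to 0.29 and 0.25. In the late window Cdh22 went from 4.77 to -0.16 and Stat3 from -0.22 to 1.00. In proximal against distal of the middle window Camk2a went from 1.5 to -0.54 and -0.057, Cdh22 from -1.94 to 0.16, Fos from -1.19 to 0.24 and Gap43 from -0.35 to 0.023, and in the late window Cdh22 went from -4.67 to 0.13 and Stat3 from 0.53 to -0.69.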

Other observations

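The comparison of late with early distal arrays, its lists, its tests of RNA quality and its overlap with the proximal response were chosen after the results were seen. Distal arrays of the letters a to c all lie in technical set A, so their time course can be read within 1 set, without sham arrays of the same set. RNA quality moved with the windows. The difference between 3' and 5' control probe sets was 0.385 to 0.514 log2 for gapdh and 1.12 to 1.44 for actin in the 9 late arrays. In 8 of the 9 early arrays it was 0.199 to 0.336 and 0.754 to 0.993, and distal 8 h b had 0.554 and 1.40. From the early (n = 9) to the late window (n = 9) Atf3 rose by 4.6 log2 (SE 0.15) and Reg3b by 4.07 (SE 0.14). Il6 rose at least 10.4-fold (log2 4.63, SE 0.10, adjusted p = 8.34e-19), Vip at least 5.35-fold (3.06, SE 0.10) and Sox11 at least 3.72-fold (1.94, SE 0.12), with early means of 4.20, 4.82 and 5.42 below the filter level. Flrt3 rose by 2.77 (SE 0.07), Gadd45a by 2.21 (SE 0.06), Gal by 1.42 (SE 0.07), Fos by 1.16 (SE 0.13), Jun by 0.86 (SE 0.05), Socs3 by 0.71 (SE 0.07) and Stat3 by 0.43 (SE 0.05). The glial genes Gfap (2.48, SE 0.13) and Sox10 (0.86, SE 0.06) rose too, and so did Timp1 (1.16), Gbp2 (1.45) and Stmn4 (1.31). The synaptic vesicle gene Syt1 fell by 1.60 (SE 0.16), the kinesin gene Kif5c by 1.43 (SE 0.18), the macrophage receptor gene Mrc1 by 1.18 (SE 0.13), Htr1d by 1.00, Grik1 by 0.85 and the neuronal transcription factor gene Isl1 by 0.78. Macrophage markers did not shift as a list, with 6 of 19 higher and 5 lower (camera adjusted p = 0.842). limma called 5910 genes (3941 higher late and 1969 lower), and 3503 with the o arrays included. Chance is excluded by 100 splits (1 as large, and 2268 at most in another). With the gapdh difference as a covariate 4072 genes were called and with that of actin 3578, of which 3740 and 3230 were also called without it in the same direction, while the standard errors grew 1.36-fold and 1.48-fold. Kif5c then fell by 0.80 and 0.65 and Syt1 by 1.07 and 0.90. In set A 3 distal arrays up to 12 h had differences as high, 8 h b, 8 h eo and 12 h c, with Atf3 up to 10.6 and Il6 up to 4.57. They lay at least 1.22 and 3.67 below the lowest of the 9 late arrays. The late o arrays of set A, outside those 9, had Atf3 at 11.51 and Il6 at 7.32 in 18 h eo, and 12 and 7.43 in 18 h fo. Distal 16 h b and c, with gapdh differences of 0.202 and 0.203, had Atf3 at 11.79 and 11.97 and Il6 at 7.94 and 8.41. These values argue against RNA quality as the whole cause of the rise of Atf3 and Il6. A rise of these genes due to the distal lesion is a hypothesis, and for the other genes a part due to RNA quality was not excluded. Against 1 h, 0 genes were called at 3 h, 717 at 8 h, 1324 at 12 h, 363 at 16 h, 2354 at 18 h, 3806 at 24 h and 3645 at 28 h.

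In this time course 43 of 48 injury-induced genes rose, 0 fell and 5 were not called (adjusted p = 5.79e-05 with an estimated correlation). The other 9 lists called were not called with an estimated correlation. Cholesterol biosynthesis had 16 of 19 higher and 0 lower (adjusted p = 0.237 with an estimated correlation), with Mvd at 0.73 (SE 0.07) and Msmo1 at 0.41 (SE 0.04), both enzymes of sterol synthesis. Glucocorticoid-responsive genes had 2 of 17 higher and 11 lower (adjusted p = 0.453 with an estimated correlation), with the kinase gene Sgk1 at -0.63 (SE 0.08) and Ddit4 at -0.78 (SE 0.10). Sensory neuron markers had 10 of 19 lower and 0 higher, satellite glia markers 8 of 11 higher and 1 lower, chemokines 11 of 22 higher and 1 lower, and unfolded protein genes 14 of 27 higher and 1 lower (adjusted p = 0.237 for each with an estimated correlation). Nociceptor genes had 22 of 43 lower and 3 higher (adjusted p = 0.09), fibroblast markers 8 of 16 lower and 1 higher (adjusted p = 0.453), with Dcn at -0.41 (SE 0.06), and pericyte markers 7 of 9 higher (adjusted p = 0.335). Skeletal muscle markers had 10 of 13 higher and 1 lower and were not called as a list, with Myl1 at 2.61 (SE 0.80), Mb at 1.47 (SE 0.45) and Acta1 at 1.09 (SE 0.47, adjusted p = 0.0596), and the calls of Myl1 and Mb ended without the 18 h arrays and with either covariate. Called lists numbered 14 with the gapdh covariate and 12 with that of actin. For the 10 lists 4 of 100 splits gave as many (11 at most and 5 at the median in the others), which bears on the count and on no single list.

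The early and late distal arrays share no array with the proximal and sham arrays of the late window. Of the 12276 genes, 535 were higher in both comparisons, where independent lists of these sizes would share 211, and 315 were lower in both, where independent lists would share 85.8. Opposite directions were seen in 17 genes that rose with the proximal lesion and fell in the distal time course and in 19 the other way. The log2 fold changes correlated at r = 0.529 across genes, which are not independent replicates. The distal comparison holds time as well as lesion, and 105 genes changed with time among sham arrays of set D, so a share of this overlap due to time or RNA quality was not excluded.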
